A study of Mus musculus with 11 samples.

How the data were processed

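Gene expression was measured in mouse cells of the C57BL/6 strain, sorted by flow cytometry from the endosteal region of bone marrow, on 11 Illumina MouseWG-6 v2 bead arrays. Per the labels, total RNA was extracted with the Qiagen RNeasy kit, some RNA samples were pooled to reach the amount needed, and biotin-labelled cRNA was made with the Illumina TotalPep kit. The labels do not say that numbered replicates come from separate animals, nor which RNA samples were pooled. The arrays fell into 4 groups by their titles: haemopoietic stem cells (HSC, LSK CD150+ CD48-, n = 2) and 3 fractions of cells positive for a fluorescein-tagged reagent that the labels call AGE, namely CD31+ B220+ (n = 3), CD31+ B220- (n = 3) and CD31- B220- (n = 3). The labels call all 3 of these fractions scavenger endothelial cells. The source names of the CD31- B220- samples begin with HSC, against their titles and cell type; the titles were followed.

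The deposited table of non-normalized values held, for each array and probe, a mean bead intensity on a linear scale without background subtraction. Beside it stood a deposited fraction headed as a detection p-value. It rose with the signal of the same array (Spearman at least 0.987 across probes), so it was read as 1 minus the detection p-value. The deposited processed values matched a log2 scale and ran from 1.57 to 14.89 on every array, with medians of 3.5 to 3.51 and the probe order of the non-normalized signals. The base of their logarithm is not given in the sources used here. Per the labels, lumi 1.1.0 was among the submitters' tools, with no role stated.

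Signals were background-corrected with limma's normexp method from the detection p-values, quantile-normalized and put on the log2 scale with an offset of 16 (the neqc function of limma 3.58.1, in R 4.3.3, with the data.table package, version 1.17.8). Of 45281 probes, 34885 carried 1 gene symbol in the annotation used here, for 19057 symbols in all. For each symbol the probe with the highest mean over the 11 arrays was kept. A gene was tested if its probe was detected, at a detection p under 0.05, on at least 2 arrays, which left 11376 genes. Probes without a single symbol (10396) were left out of the tested genes because they cannot be tied to 1 gene, and were tested apart, in a fit of all probes detected on at least 2 arrays.

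All 11 arrays entered a single linear model with 1 mean per group, so that the pair of HSC arrays shared the estimate of spread with the other groups. The 6 pairwise contrasts were tested with limma's moderated test, 2-sided, and the 3 fractions together with its F-test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 11376 genes of each comparison. Log2 differences are the first-named group minus the second. Where no array of the dimmer group detected a gene, its fold is a lower bound. The bound is the brighter group's mean minus the mean over the dim arrays of the larger of the gene's value and the lowest detected value of that array, and it is written "at least". Named genes that only some arrays of the dimmer group detected are given by the same bound, a choice made after the data were seen, and they are not among the bounds counted per comparison. The number of arrays limits the precision of every value.

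Gene lists were fixed before the data were examined, as were the groups, the tests and the alternatives listed here, except where a later choice is named. The 22 lists held the sorting-marker genes, scavenger receptors, sinusoidal endothelial genes, pan-endothelial genes, haemopoietic stem cell genes, endothelial-to-haemopoietic transcription factors, B lineage, plasma cell, plasmacytoid dendritic cell, conventional dendritic cell, MHC class II, macrophage and monocyte, neutrophil and granule, basophil, mast cell and eosinophil, erythroid, megakaryocyte and platelet, T and NK cell, stromal and osteoblast, cell cycle, lysosome and endocytosis, interferon response, and immediate early and heat shock genes. Of their 641 entries, 596 had a named probe and 501 were tested; 28 genes were in more than 1 list. Each list was compared with all other tested genes by camera, limma's competitive set test, with a preset inter-gene correlation of 0.01 and adjustment over 132 list tests. The tests were repeated with an estimated correlation. Calls were also counted with p adjusted over the list alone. The sorting-marker list holds genes of the markers used in the gates, and the stem cell list holds Kit and Slamf1 among them. The sort thus set part of the outcome of these lists. The B220 gates also bear on the B lineage list, since B cells carry B220. LSK stands for lineage-negative, Sca-1+ and Kit+, so by its name the HSC gate leaves out cells with markers of mature blood lineages. The sort may thus have set part of the differences of the blood lineage lists from HSC too.

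The genes named were chosen by rule in each comparison. They were the sorting-marker genes; the 5 largest changes in each direction among called genes detected on every array of both groups, without overlap between the groups; the 5 largest bounds in each direction among called genes detected on every array of 1 group and on none of the other; and up to 4 members of each list with the smallest adjusted p. Names that are not gene symbols were passed over among the largest changes and bounds.

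The alternatives were no background correction, normexp without detection p-values at an offset of 50, scaling to a common median in place of quantile normalization, the deposited processed values, no filter, a filter of detection p under 0.01 on at least 3 arrays, all probes singly, the compared groups alone, replicate number as a block, array weights, an intensity trend with robust estimation, a minimum log2 change of 1 (limma's treat), and leaving out each array in turn. List counts without CD31- B220- replicate 3 were added after the data were seen. The linear model and its calls, with all groups fitted together, were tested on simulated log2 values of 11376 genes with 200 changed, in 5 runs. With 3 arrays against 3 the model recovered 52.1% of log2 changes of 1 and 94.3% of log2 changes of 2, with 4.3% false calls. With 3 against 2 it recovered 44.3% and 93%, with 3.4% false calls. Background correction, normalization, the detection filter and the brightness of the HSC arrays were not part of the simulation. In the data 29.4% to 50.2% of genes were called per comparison, far more than were changed in the simulation. The simulated rates therefore describe the model alone and may not hold for these data. Plots were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.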

Results

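Expression was measured on 2 arrays of haemopoietic stem cells (HSC) and on 9 arrays of AGE-positive cells, 3 for each of the CD31+ B220+, CD31+ B220- and CD31- B220- fractions. Before normalization the 75th percentile of probe signals lay between 376.8 and 450.5 on the HSC arrays and between 145.9 and 211.6 on the others. Each HSC array detected 17557 to 17755 of the 45281 probes, and each array of the fractions 15063 to 17418. After normalization, arrays of 1 group correlated across genes with a median Pearson r of 0.975 to 0.989. Arrays of different groups had medians from 0.805, for CD31+ B220+ with CD31- B220-, to 0.897, for CD31+ B220- with CD31- B220-. Genes are not independent replicates in these correlations. The first principal component held 43.1% of the variance and ordered the fractions from CD31+ B220+ through CD31+ B220- to CD31- B220-, while the second, with 31.5%, set the HSC arrays apart. CD31- B220- replicate 3 correlated more closely with the CD31+ B220- arrays (mean r 0.919) than the other two of its group did (0.892 and 0.893), and its mean r within its own group was 0.974.

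**Figure D1:**
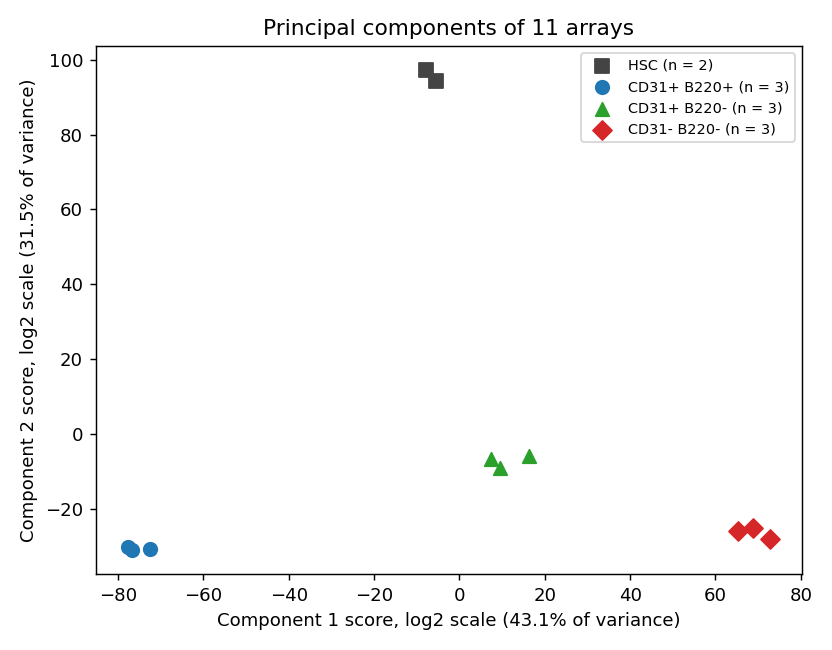
The 11 arrays on the first (43.1% of variance) and second (31.5%) principal components of the tested genes, 1 point per array and coloured by group. The HSC arrays sit at 94.3 to 97.2 on the second component, above every array of the 3 fractions.

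The genes of the sorting markers gave each group a different profile. Kit, the stem cell factor receptor, had a mean log2 signal of 13.10 ± 0.14 (SD, n = 2) in HSC, 9.92 ± 0.35 (n = 3) in CD31+ B220- cells, 8.62 ± 0.25 (n = 3) in CD31- B220- cells and 5.52 ± 0.30 (n = 3) in CD31+ B220+ cells. Pecam1, which encodes CD31, was at 9.48 ± 0.14 (n = 3) in CD31+ B220+ and 7.85 ± 0.36 (n = 3) in CD31+ B220- cells. In CD31- B220- cells it was at 5.12 ± 0.15 (n = 3), detected on 1 of 3 arrays, and in HSC at 7.18 ± 0.40 (n = 2). Slamf1, which encodes CD150, was detected on both HSC arrays (7.76 ± 0.10, n = 2), on 2 of 3 arrays of CD31+ B220+ cells (5.74 ± 0.73, n = 3) and on no array of the CD31+ B220- and CD31- B220- fractions. Cd48 was detected on all 9 arrays of the fractions and on neither HSC array. Ptprc, whose protein CD45 carries the B220 epitope in B cells, had its highest mean in CD31+ B220+ cells, at 7.59 ± 0.16 (n = 3), although median scaling placed it below HSC. Ly6a, which encodes Sca-1, had no probe with a gene name used here.

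**Figure D2:**
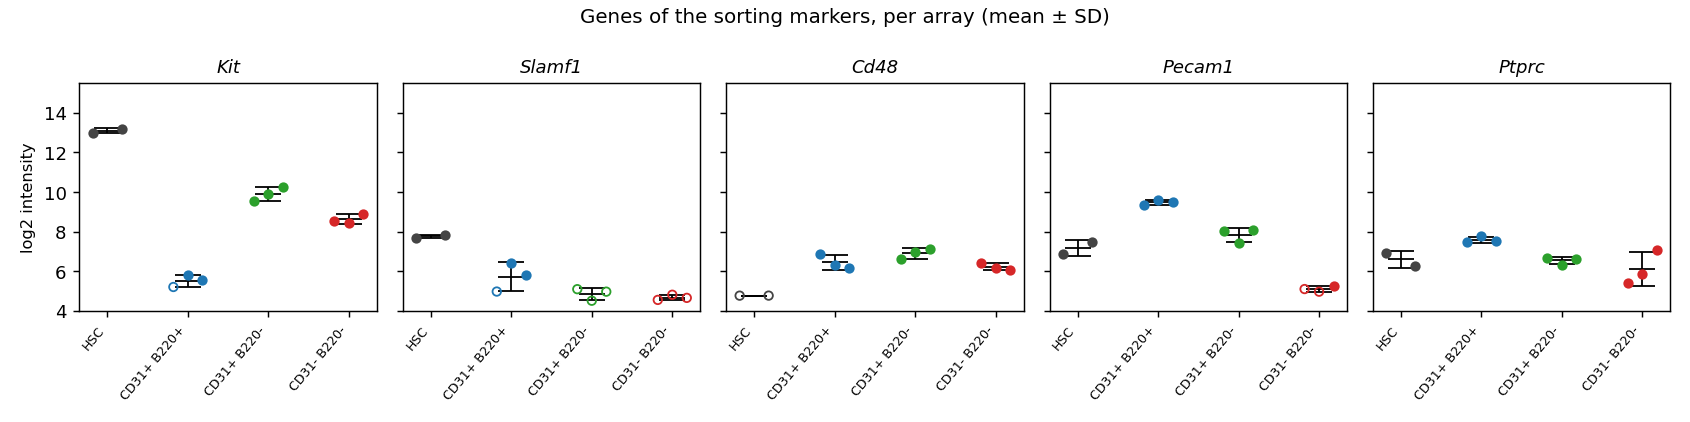
Log2 signal of Kit, Slamf1, Cd48, Pecam1 and Ptprc on each of the 11 arrays, with filled points where the gene was detected, open points where it was not, and bars for the mean ± SD of each group. Kit averaged 13.10 in HSC, and Pecam1 averaged 9.48 in CD31+ B220+ and 5.12 in CD31- B220- cells.

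The series asks about adult marrow cells that can give rise to both vessel lining and blood, so each fraction was first set against HSC and the fractions were then set against one another. The 3 comparisons with HSC share the same 2 HSC arrays, and in all of them the difference in cell type coincides with the difference in array brightness. The labels number the HSC samples apart from the fractions, whose numbers follow one another, and do not say whether the HSC arrays were run separately, so a run of their own could not be told apart from cell type either.

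In CD31+ B220+ cells all 28 tested B lineage genes were higher than in HSC, a difference that the sort for B220 may have set in part. Vpreb3, a chaperone of the pre-B cell receptor, was 460-fold higher, at 14.20 ± 0.06 (n = 3) against 5.35 ± 0.11 (n = 2) in HSC (adjusted p = 2.85e-10). Fcmr, the IgM Fc receptor, was at least 413-fold higher, Ly6d at least 368-fold and Pou2af1, a B cell coactivator, at least 263-fold. In the other direction Kit was at least 182-fold lower (adjusted p = 2.55e-10), Ifitm1 279-fold lower (6.69 ± 0.30, n = 3, against 14.81 ± 0.07, n = 2; adjusted p = 2.55e-10) and Esam, an endothelial junction protein that HSC also carry, at least 128-fold lower. Of 11376 genes tested, 5152 differed, 2192 higher and 2960 lower, and 1266 and 1954 of these by at least 2-fold. For 1244 the fold is known only as a bound.

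Among the blood lineages, B lineage genes (28 of 28 higher, the same count adjusted over the list alone; adjusted p = 1.85e-24) had a median log2 difference of 5.26, or 4.90 with undetected genes at their bound. Of 13 plasma cell genes 6 were higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.000911). Irf4 was at least 72.5-fold higher. In the plasmacytoid dendritic cell list 14 of 22 genes were higher and 2 lower (15 and 3 adjusted over the list alone; adjusted p = 3.16e-05, and adjusted p = 0.107 with an estimated correlation). Spib, a transcription factor also used by B cells, was at least 58.9-fold higher. The conventional dendritic cell list had 8 of 18 genes higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.09 with an estimated correlation). Antigen presentation genes of MHC class II were higher for 10 of 11 (10 adjusted over the list alone; adjusted p = 1.49e-09, and adjusted p = 0.093 with an estimated correlation). Cd74, the invariant chain, was 71.3-fold higher and H2-Eb1 66.4-fold. Cell cycle genes were higher for 15 of 41 and lower for 3 (15 and 3 adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.633 with an estimated correlation), but under median scaling 2 were higher and 24 lower. Their median there, -0.89, still lay above the all-gene median of -1.19, and the list's adjusted p was 0.25 (0.00932 to 0.633 over 5 alternatives).

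Genes of stem cells and of vessel lining were lower in CD31+ B220+ cells than in HSC. Of 32 stem cell genes 27 were lower and 1 higher (28 and 1 adjusted over the list alone; adjusted p = 2.89e-13), with a median of -3.17, or -2.87 with bounds. Pan-endothelial genes were lower for 17 of 25 and higher for 2 (17 and 3 adjusted over the list alone; adjusted p = 7.74e-07). Robo4, an endothelial guidance receptor, was at least 45.2-fold lower and Eng, a coreceptor for TGF-beta, at least 27.8-fold. Megakaryocyte genes were lower for 14 of 21 and higher for 0 (15 and 0 adjusted over the list alone; adjusted p = 8.34e-07), among them Vwf, at least 23.3-fold. Transcription factors of the endothelial-to-haemopoietic transition were lower for 9 of 18 and higher for 1 (9 and 2 adjusted over the list alone; adjusted p = 0.0396, and adjusted p = 0.146 with an estimated correlation). Gata2 was at least 119-fold lower and Tal1 at least 45.3-fold. That list's adjusted p was 0.109 under median scaling and 0.0591 with the deposited processed values (0.0243 to 0.146 over 5 alternatives). Erythroid genes were lower for 15 of 29 and higher for 2 (15 and 2 adjusted over the list alone; adjusted p = 0.00298, and adjusted p = 0.267 with an estimated correlation). Their adjusted p was 0.0831 under median scaling (0.00213 to 0.267 over 5 alternatives).

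The other 11 lists did not pass in this comparison, with adjusted p from 0.0965 to 0.862. Counts higher and lower were 3 and 2 of 5 for sorting-marker genes, 2 and 1 of 15 for scavenger receptors, 2 and 4 of 15 for sinusoidal endothelial genes, 1 and 9 of 28 for macrophage genes, 0 and 4 of 28 for neutrophil genes and 1 and 6 of 15 for basophil and mast cell genes. They were 4 and 7 of 21 for T and NK cell genes, 2 and 8 of 28 for stromal genes, 10 and 14 of 37 for lysosome genes, 5 and 6 of 27 for interferon genes, and 6 and 9 of 24 for immediate early genes. Adjusted over the list alone these were the same, except 1 and 8 for macrophage, 0 and 3 for neutrophil and 11 and 14 for lysosome genes. Median scaling turned sorting-marker genes to 1 higher and 2 lower and scavenger receptors to 2 and 9. Scavenger receptors were at 2 and 4 with normexp without detection p-values and at 2 and 5 with the deposited processed values. Sorting-marker genes had a median of 0.99 and a mean of -0.92, and immediate early genes a median of 0.03 and a mean of -0.09. Scaling to a common median moved the median of all genes to -1.19 and left 9.5% of 8374 called genes higher, against 42.5% of 5152. Of 4008 genes called in both, 436 changed direction, and Ptprc (1.98-fold higher, adjusted p = 0.0459) was at -0.598 there. Its call also ended without any 1 of 9 arrays, all except CD31- B220- replicates 1 and 3 (adjusted p = 0.0507 to 0.318, and 0.00126 to 1 over 23 alternatives), and with a replicate block (0.829, adjusted p = 0.0953), the deposited processed values (adjusted p = 0.137) and no filter (0.081).

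Single genes of myeloid and B lineage kinds were higher in CD31+ B220- cells than in HSC. Chil3, a secreted lectin of macrophages and neutrophils, was 131-fold higher, at 12.96 ± 0.38 (n = 3) against 5.93 ± 0.13 (n = 2; adjusted p = 4.69e-09). F13a1, a coagulation factor made by monocytes, was 95.6-fold higher, at 13.64 ± 0.12 (n = 3) against 7.06 ± 0.03 (n = 2; adjusted p = 1.49e-09). Igll1, a surrogate light chain of pre-B cells, was 89.5-fold higher and Fn1, fibronectin, at least 90.9-fold. Nkx2-3 was 52-fold lower and Esam 28-fold lower (7.55 ± 0.18, n = 3, against 12.36 ± 0.01, n = 2). In all, 4835 genes differed, 2075 higher and 2760 lower, of which 1245 and 1695 by at least 2-fold, and 912 folds are known only as bounds.

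Genes of the scavenger receptor list were higher for 9 of 15 and lower for 1 (9 and 1 adjusted over the list alone, adjusted p = 0.000574, and adjusted p = 0.0607 with an estimated correlation). Lgals3 was 50.5-fold higher, Fcgr2b 31.9-fold and Clec7a, a receptor for fungal glucans, at least 15.1-fold, while Scarf1 was 20.2-fold lower. Macrophage and monocyte genes were higher in this fraction too, so these values do not single out endothelial cells. Lysosome and endocytosis genes were higher for 18 of 37 and lower for 5 (21 and 7 adjusted over the list alone; adjusted p = 0.00142, and adjusted p = 0.385 with an estimated correlation), although median scaling gave 6 higher and 13 lower. Their median there was -0.25, above the all-gene median of -1.11. Pan-endothelial genes were lower for 15 of 25 and higher for 4 (16 and 4 adjusted over the list alone; adjusted p = 7.21e-05). Robo4 was 19.6-fold, Emcn 17.3-fold and Eng 7.68-fold lower. Stem cell genes were lower for 28 of 32 and higher for 0 (28 and 0 adjusted over the list alone; adjusted p = 4.61e-14), among them Ndn, at least 62.3-fold, and Meis1, 13.2-fold. Megakaryocyte genes were lower for 13 of 21 and higher for 0 (13 and 0 adjusted over the list alone; adjusted p = 0.000203). Transition transcription factors were lower for 9 of 18 and higher for 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0202, and adjusted p = 0.11 with an estimated correlation); median scaling gave adjusted p = 0.0793 (0.00804 to 0.11 over 5 alternatives). Erythroid genes were lower for 12 of 29 and higher for 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0329, and adjusted p = 0.436 with an estimated correlation). Their adjusted p was 0.0625 without background correction and 0.158 under median scaling (0.0277 to 0.436 over 5 alternatives).

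Macrophage and monocyte genes were higher for 22 of 28 and lower for 1 (23 and 2 adjusted over the list alone; adjusted p = 1.18e-11, and adjusted p = 0.0789 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, was at least 24.5-fold higher and Adgre1, which encodes F4/80, at least 15.8-fold. Neutrophil and granule genes were higher for 20 of 28 and lower for 0 (20 and 0 adjusted over the list alone; adjusted p = 4.5e-09, and adjusted p = 0.186 with an estimated correlation). Basophil, mast cell and eosinophil genes were higher for 9 of 15 and lower for 3 (11 and 3 adjusted over the list alone; adjusted p = 0.00307, and adjusted p = 0.0581 with an estimated correlation). Hdc, which makes histamine, was 27.3-fold higher and Cpa3, a mast cell protease, 10.8-fold. B lineage genes were higher for 23 of 28 and lower for 0 (23 and 0 adjusted over the list alone; adjusted p = 8.2e-15). Vpreb3 was 72.4-fold and Il7r at least 19.8-fold higher.

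Plasma cell genes were higher for 10 of 13 and lower for 0 (10 and 0 adjusted over the list alone; adjusted p = 2.67e-05). For plasmacytoid dendritic cells the count was 15 of 22 higher and 2 lower (16 and 2 adjusted over the list alone; adjusted p = 2.15e-05, and adjusted p = 0.101 with an estimated correlation). For conventional dendritic cells it was 9 of 18 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.000263). MHC class II genes were higher for 9 of 11 and lower for 0 (10 and 0 adjusted over the list alone; adjusted p = 3.15e-06, and adjusted p = 0.159 with an estimated correlation). T and NK cell genes were higher for 14 of 21 and lower for 1 (14 and 2 adjusted over the list alone; adjusted p = 9.57e-05, and adjusted p = 0.187 with an estimated correlation). Cd3d, a chain of the T cell receptor complex, was at least 10.2-fold higher. Cell cycle genes were higher for 29 of 41 and lower for 1 (30 and 1 adjusted over the list alone; adjusted p = 4.26e-11, and adjusted p = 0.221 with an estimated correlation), including Aurkb, a mitotic kinase, 9.62-fold.

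Of the other 5 lists, none passed (adjusted p from 0.0836 to 0.725). Sinusoidal endothelial genes were higher for 7 of 15 and lower for 3, turning to 5 and 6 under median scaling, where the list passed (adjusted p = 0.0177; 0.0177 to 0.186 over 5 alternatives) with a median of -0.03 against -1.11 for all genes. Sorting-marker genes were higher for 2 of 5 and lower for 2, stromal genes for 2 and 6 of 28, interferon genes for 3 and 6 of 27, and immediate early genes for 5 and 8 of 24. Adjusted over the list alone all 5 kept these counts, except 2 and 5 for stromal genes. Median scaling moved the median of all genes to -1.11 and left 11.2% of 8232 called genes higher, against 42.9% of 4835, with 226 of the 3705 called in both changing direction. Pecam1 (1.59-fold, adjusted p = 0.0418) was at -0.845 under that scaling, and its call ended without HSC replicate 1, CD31+ B220+ replicates 2 or 3, or CD31+ B220- replicates 1 or 3 (adjusted p = 0.0512 to 0.369, and 0.0119 to 1 over 23 alternatives). That call also ended with a replicate block (0.601, adjusted p = 0.0886), the deposited processed values (adjusted p = 0.0859), the compared groups alone (0.0695), no filter (0.0519) and all probes singly (0.0504). Ptprc, at -0.051 with an adjusted p of 0.925, was at -1.446 with an adjusted p of 0.00185 under median scaling (0.00185 to 1 over 23 alternatives).

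The erythroid list and single genes of stromal and myeloid kinds were higher in CD31- B220- cells than in HSC. Car1, a carbonic anhydrase of red cell precursors, was 75.5-fold higher, at 13.32 ± 0.33 (n = 3) against 7.08 ± 0.33 (n = 2; adjusted p = 3.78e-07). Col5a1, a fibrillar collagen, was 35.7-fold higher (10.55 ± 0.33, n = 3, against 5.39 ± 0.15, n = 2), and Chil3 113-fold higher (adjusted p = 3.1e-09). Meis1, a stem cell transcription factor, was 84.5-fold lower (adjusted p = 2.64e-10), and Esam at least 131-fold lower. In all, 5713 genes differed, 2438 higher and 3275 lower, of which 1554 and 2159 by at least 2-fold, and 1213 folds are known only as bounds.

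Erythroid genes were higher for 26 of 29 and lower for 0 (26 and 0 adjusted over the list alone; adjusted p = 3.96e-17). Kel was 57.5-fold and Tfrc, the transferrin receptor, 20.5-fold higher. Stromal and osteoblast genes were higher for 20 of 28 and lower for 1 (20 and 2 adjusted over the list alone; adjusted p = 2.98e-06, and adjusted p = 0.159 with an estimated correlation). Adipoq, which encodes adiponectin, was at least 9.41-fold higher and Ebf3 at least 7.03-fold. Cell cycle genes were higher for 36 of 41 and lower for 0 (36 and 1 adjusted over the list alone; adjusted p = 8.2e-15, and adjusted p = 0.162 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was 17.2-fold higher. Macrophage genes were higher for 19 of 28 and lower for 2 (19 and 2 adjusted over the list alone; adjusted p = 1.2e-06, and adjusted p = 0.162 with an estimated correlation). F13a1 was 61-fold higher. Neutrophil genes were higher for 20 of 28 and lower for 0 (21 and 1 adjusted over the list alone; adjusted p = 1.59e-07, and adjusted p = 0.224 with an estimated correlation). Cd177 was at least 39.6-fold higher. Scavenger receptors were higher for 10 of 15 and lower for 1 (10 and 1 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.0954 with an estimated correlation), among them Lgals3, 33.2-fold.

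Plasma cell genes were higher for 6 of 13 and lower for 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0287, and adjusted p = 0.113 with an estimated correlation); without background correction the adjusted p was 0.0727 (0.00058 to 0.113 over 5 alternatives). Conventional dendritic cell genes were higher for 9 of 18 and lower for 2 (9 and 3 adjusted over the list alone; adjusted p = 0.0174, and adjusted p = 0.131 with an estimated correlation). Pan-endothelial genes were lower for 18 of 25 and higher for 3 (18 and 3 adjusted over the list alone; adjusted p = 6.99e-06). Robo4 was at least 51.7-fold and Emcn, endomucin, at least 26-fold lower. Stem cell genes were lower for 28 of 32 and higher for 1 (28 and 1 adjusted over the list alone; adjusted p = 8.38e-11). Transition transcription factors were lower for 12 of 18 and higher for 1 (12 and 2 adjusted over the list alone; adjusted p = 0.00684, and adjusted p = 0.0789 with an estimated correlation). Gata2 was 74.7-fold and Gfi1 12.8-fold lower. Megakaryocyte genes were lower for 13 of 21 and higher for 0 (14 and 0 adjusted over the list alone; adjusted p = 0.000109). Pf4, platelet factor, was at least 18.8-fold lower.

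For the other 10 lists the adjusted p was 0.0589 to 0.666. Counts higher and lower were 10 and 3 of 28 for B lineage, 16 and 6 of 37 for lysosome, 4 and 2 of 11 for MHC class II, 10 and 3 of 27 for interferon, 5 and 3 of 22 for plasmacytoid dendritic cell and 5 and 3 of 15 for sinusoidal endothelial genes. They were 1 and 3 of 5 for sorting-marker, 3 and 5 of 15 for basophil and mast cell, 0 and 5 of 21 for T and NK cell and 4 and 7 of 24 for immediate early genes. Adjusted over the list alone these held, except 17 and 6 for lysosome, 5 and 2 for MHC class II and 3 and 6 for basophil and mast cell genes. Median scaling turned lysosome genes to 6 and 15, MHC class II to 3 and 5, interferon to 1 and 15, plasmacytoid dendritic cell to 4 and 7 and sinusoidal genes to 3 and 7. Under it the B lineage list passed (adjusted p = 5.64e-05), as with the deposited processed values (adjusted p = 0.0279; 5.64e-05 to 0.549 over 5 alternatives). The plasmacytoid dendritic cell list passed under it as well (adjusted p = 0.0473; 0.0473 to 0.72 over 5 alternatives), and the lysosome list with the deposited processed values (adjusted p = 0.0491; 0.0491 to 0.609 over 5 alternatives). Sinusoidal genes had a median of -0.15 and a mean of 0.04, and T and NK cell genes a median of 0.02 and a mean of -0.30. Median scaling moved the median of all genes to -1.04 and left 13.8% of 8049 called genes higher, against 42.7% of 5713, with 169 of the 4392 called in both changing direction. Without CD31- B220- replicate 3, erythroid genes stayed at 26 higher and stromal genes at 20, cell cycle genes were at 37 and neutrophil genes at 18, and Ptprc, at -0.487 with an adjusted p of 0.301, was at -0.962 with an adjusted p of 0.00917; median scaling gave -1.893 with an adjusted p of 0.000147 (0.000147 to 1 over 23 alternatives).

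**Figure D3:**
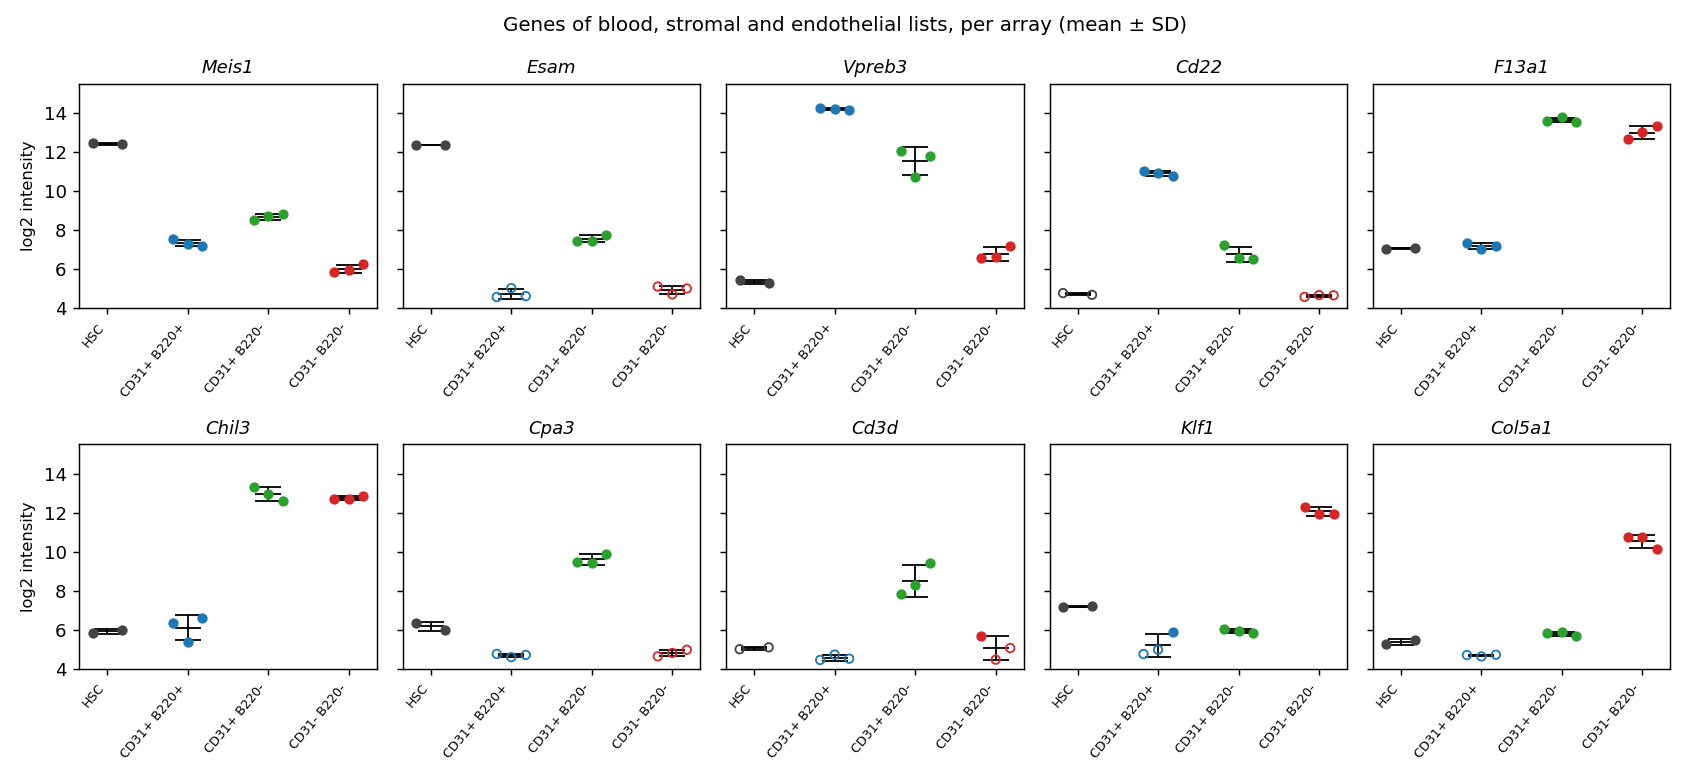
Log2 signal of 10 named genes (Meis1, Esam, Vpreb3, Cd22, F13a1, Chil3, Cpa3, Cd3d, Klf1 and Col5a1) on each of the 11 arrays, with filled points where detected, open points where not, and bars for the mean ± SD of each group. Vpreb3 averaged 14.20 in CD31+ B220+ cells, F13a1 13.64 in CD31+ B220- cells and Col5a1 10.55 in CD31- B220- cells.

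Among the 3 fractions, 6056 of 11376 genes (53.2%) differed by the F-test. Genes higher in 1 group than in each of the other groups numbered 1626 for HSC, 919 for CD31+ B220+, 295 for CD31+ B220- and 811 for CD31- B220- cells.

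CD31+ B220+ cells had higher B lineage genes than CD31+ B220- cells and lower macrophage, basophil or mast cell and scavenger receptor genes. B220 separated CD31+ B220+ cells from both other fractions, so the sort may have set part of their B lineage differences. Il4i1 was 45.9-fold higher (12.98 ± 0.40 against 7.46 ± 0.56, n = 3 each; adjusted p = 6.67e-09) and Tnfrsf13c, the BAFF receptor of B cells, 23.5-fold (12.50 ± 0.05 against 7.95 ± 0.62, n = 3 each; adjusted p = 3.95e-08). F13a1 was 88.7-fold lower (7.17 ± 0.16 against 13.64 ± 0.12, n = 3 each; adjusted p = 1.44e-10), Chil3 115-fold lower and Fn1 at least 79.5-fold lower. Pecam1 was 3.09-fold higher (adjusted p = 5.64e-05) and Kit at least 20-fold lower. In all, 4142 genes differed, 1981 higher and 2161 lower, of which 967 and 1290 by at least 2-fold, and 640 folds are known only as bounds. Median scaling gave 36.3% of 3312 called genes as higher, against 47.8%.

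B lineage genes were higher for 24 of 28 and lower for 0 (24 and 1 adjusted over the list alone; adjusted p = 1.18e-15), among them Rag1, the recombinase of antigen receptor genes, 14.6-fold, and Cd22 17.7-fold. MHC class II genes were higher for 9 of 11 and lower for 0 (9 and 0 adjusted over the list alone; adjusted p = 3.47e-06, and adjusted p = 0.16 with an estimated correlation). Ciita, their master regulator, was 8.09-fold higher. Macrophage genes were lower for 27 of 28 and higher for 0 (27 and 0 adjusted over the list alone; adjusted p = 6.41e-20). Csf1r was at least 19.5-fold and Adgre1 at least 13.8-fold lower. Neutrophil genes were lower for 20 of 28 and higher for 0 (21 and 0 adjusted over the list alone; adjusted p = 1.08e-11, and adjusted p = 0.146 with an estimated correlation). Hp, haptoglobin, was at least 119-fold lower. Basophil, mast cell and eosinophil genes were lower for 11 of 15 and higher for 0 (11 and 0 adjusted over the list alone; adjusted p = 4.98e-06). Hdc was 25.4-fold and Cpa3 at least 19-fold lower. T and NK cell genes were lower for 15 of 21 and higher for 2 (16 and 2 adjusted over the list alone; adjusted p = 7.27e-06, and adjusted p = 0.157 with an estimated correlation). Thy1 was at least 15.3-fold lower and Cd2 9.1-fold higher. Megakaryocyte genes were lower for 11 of 21 and higher for 0 (12 and 0 adjusted over the list alone; adjusted p = 0.000188).

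Scavenger receptors were lower for 11 of 15 and higher for 0 in CD31+ B220+ cells (11 and 0 adjusted over the list alone; adjusted p = 3.38e-05). Lgals3 was 64-fold, Mrc1, the mannose receptor, at least 3.95-fold and Cd163 at least 2.22-fold lower. Sinusoidal endothelial genes were lower for 9 of 15 and higher for 1 (10 and 1 adjusted over the list alone; adjusted p = 0.00114). Vcam1, an adhesion molecule, was 9.23-fold lower. Pan-endothelial genes were lower for 13 of 25 and higher for 2 (13 and 2 adjusted over the list alone; adjusted p = 7.21e-05). Adgrl4 was at least 13.7-fold and Eng at least 3.62-fold lower. Stem cell genes were lower for 11 of 32 and higher for 4 (12 and 4 adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.0789 with an estimated correlation). Lysosome genes were lower for 21 of 37 and higher for 3 (22 and 3 adjusted over the list alone; adjusted p = 1.98e-05, and adjusted p = 0.244 with an estimated correlation). Sort1 was 22-fold and Ctsb, a cathepsin, 2.64-fold lower. Cell cycle genes were lower for 29 of 41 and higher for 0 (30 and 0 adjusted over the list alone; adjusted p = 8.11e-09, and adjusted p = 0.273 with an estimated correlation). Tyms, thymidylate synthase, was 4.17-fold lower.

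The other 9 lists did not pass between these fractions (adjusted p from 0.125 to 0.795). Counts higher and lower were 3 and 1 of 5 for sorting-marker genes, 3 and 5 of 18 for transition transcription factors, 4 and 4 of 13 for plasma cell, 8 and 6 of 22 for plasmacytoid and 6 and 5 of 18 for conventional dendritic cell genes. They were 2 and 6 of 29 for erythroid, 0 and 5 of 28 for stromal, 3 and 7 of 27 for interferon and 8 and 7 of 24 for immediate early genes; adjusted over the list alone, conventional dendritic cell genes were at 6 and 6, immediate early genes at 9 and 7, and the others as before. Median and mean differed in sign for sorting-marker (0.88 and -0.26), plasmacytoid (-0.25 and 0.40) and conventional dendritic cell (-0.02 and 0.24) and stromal genes (0.02 and -0.26). Ptprc was 2.05-fold higher (adjusted p = 0.0267), a call that ended without replicate 2 or 3 of either fraction (adjusted p = 0.0511 to 0.0863, and 0.000634 to 1 over 23 alternatives), and so did that of Slamf1, at least 1.39-fold higher (adjusted p = 0.0332; 0.0565 to 0.162 without those arrays, and 0.0016 to 1 over 23 alternatives). Median scaling, the deposited processed values and no filter ended both calls (adjusted p = 0.0648, 0.107 and 0.0522 for Ptprc; 0.0575, 0.0583 and 0.0594 for Slamf1), and the compared groups alone that of Slamf1 (0.0823). Cd48, at -0.44 with an adjusted p of 0.141, was at -0.655 with an adjusted p of 0.0315 without CD31+ B220+ replicate 1 and at -0.568 with an adjusted p of 0.0352 with array weights (0.0315 to 1 over 23 alternatives).

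CD31+ B220- cells had lower erythroid genes than CD31- B220- cells and higher basophil or mast cell genes. Klf1, the erythroid master regulator, was 69.7-fold lower, at 5.94 ± 0.11 (n = 3) against 12.07 ± 0.21 (n = 3; adjusted p = 1.83e-09), and Col5a1 27-fold lower. Igll1 was 44.3-fold higher (11.80 ± 0.56 against 6.33 ± 0.63, n = 3 each; adjusted p = 4.21e-08), and Cpa3 at least 19.4-fold higher. Pecam1 was at least 5.7-fold higher (adjusted p = 5.63e-07) and Kit 2.45-fold higher. In all, 3345 genes differed, 1908 higher and 1437 lower, of which 996 and 821 by at least 2-fold, and 503 folds are known only as bounds. Median scaling gave 53.9% of 2603 called genes as higher, against 57%.

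Every 1 of 29 erythroid genes was lower in CD31+ B220- cells (29 adjusted over the list alone; adjusted p = 8.18e-34), with a median of -4.46, or -4.34 with bounds. Trim10 was at least 85.6-fold lower. Stromal genes were lower for 21 of 28 and higher for 2 (22 and 2 adjusted over the list alone; adjusted p = 3.6e-13, and adjusted p = 0.0581 with an estimated correlation). Gas6, a ligand of TAM receptors, was at least 8.99-fold lower. Cell cycle genes were lower for 16 of 41 and higher for 0 (19 and 0 adjusted over the list alone; adjusted p = 3.36e-06, and adjusted p = 0.385 with an estimated correlation). Ccne1, cyclin E1, was 5.56-fold lower. Interferon response genes were lower for 9 of 27 and higher for 1 (10 and 1 adjusted over the list alone; adjusted p = 0.00547, and adjusted p = 0.445 with an estimated correlation). Rsad2, viperin, was 5.64-fold and Isg15 4.55-fold lower. Pan-endothelial genes were higher for 11 of 25 and lower for 2 (13 and 3 adjusted over the list alone; adjusted p = 0.00387, and adjusted p = 0.0503 with an estimated correlation). Esam was at least 4.66-fold and Icam2 4.07-fold higher. Sinusoidal genes were higher for 6 of 15 and lower for 0 (7 and 0 adjusted over the list alone; adjusted p = 0.0217, and adjusted p = 0.11 with an estimated correlation). Among these were Stab2, a hyaluronan receptor of sinusoids, at least 1.58-fold, and Mrc1, 2.32-fold. Sorting-marker genes were higher for 3 of 5 and lower for 0 (3 and 0 adjusted over the list alone, adjusted p = 0.0251, and adjusted p = 0.159 with an estimated correlation). Pecam1 is among them and encodes CD31, by which these fractions were sorted apart, so its direction was set by the sort.

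B lineage genes were higher in CD31+ B220- cells for 21 of 28 and lower for 1 (21 and 1 adjusted over the list alone; adjusted p = 2.13e-13, and adjusted p = 0.0507 with an estimated correlation). Il7r was 14.7-fold and Cd72 at least 21.1-fold higher. Plasma cell genes were higher for 6 of 13 and lower for 0 (7 and 0 adjusted over the list alone; adjusted p = 0.00625, and adjusted p = 0.0743 with an estimated correlation). Plasmacytoid dendritic cell genes were higher for 16 of 22 and lower for 0 (16 and 2 adjusted over the list alone; adjusted p = 1.96e-06, and adjusted p = 0.0789 with an estimated correlation). MHC class II genes were higher for 9 of 11 and lower for 0 (11 and 0 adjusted over the list alone; adjusted p = 2.55e-05, and adjusted p = 0.187 with an estimated correlation). Basophil, mast cell and eosinophil genes were higher for 9 of 15 and lower for 0 (11 and 0 adjusted over the list alone; adjusted p = 3.87e-06). Prss34, a basophil and mast cell protease, was at least 41.8-fold higher. T and NK cell genes were higher for 16 of 21 and lower for 0 (16 and 0 adjusted over the list alone; adjusted p = 2.79e-08, and adjusted p = 0.0954 with an estimated correlation). Cd3d was at least 8.31-fold and Thy1 8.43-fold higher.

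In this comparison the other 9 lists did not pass (adjusted p from 0.0907 to 0.665). Counts higher and lower were 6 and 3 of 15 for scavenger receptors, 9 and 4 of 32 for stem cell genes, 7 and 3 of 18 for transition transcription factors, 4 and 1 of 18 for conventional dendritic cell and 8 and 2 of 28 for macrophage genes. They were 6 and 7 of 28 for neutrophil, 7 and 1 of 21 for megakaryocyte, 11 and 3 of 37 for lysosome and 7 and 3 of 24 for immediate early genes; adjusted over the list alone, stem cell genes were at 10 and 4, transition factors at 9 and 4, lysosome genes at 12 and 3 and the others as before. Neutrophil genes had a median of -0.09 and a mean of 0.06. Without CD31- B220- replicate 3, erythroid genes were lower for 28 and stromal genes for 22, neutrophil genes were at 8 higher and 4 lower, and lysosome genes at 18 and 3. Ptprc, at 0.44 with an adjusted p of 0.382, was at 0.911 with an adjusted p of 0.0118 without that array (0.0118 to 1 over 23 alternatives). The call of Cd48 (1.6-fold higher, adjusted p = 0.0316) ended without replicate 2 or 3 of either fraction (adjusted p = 0.0802 to 0.124, and 0.0163 to 1 over 23 alternatives), as it did without background correction (0.0547), with normexp without detection p-values (0.0507) and with an intensity trend (0.0563).

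CD31+ B220+ and CD31- B220- cells lay furthest apart among the fractions, with B lineage genes higher in the first and erythroid genes higher in the second. Vpreb3 was 171-fold higher in CD31+ B220+ cells, at 14.20 ± 0.06 (n = 3) against 6.78 ± 0.35 (n = 3; adjusted p = 3.25e-10), and Pecam1 at least 17.6-fold higher (adjusted p = 2.17e-09). Aqp1, the water channel of red cells, was 78.8-fold lower, at 7.46 ± 0.69 (n = 3) against 13.76 ± 0.19 (n = 3; adjusted p = 6.26e-10). Ccl9, a chemokine, was 100-fold lower (adjusted p = 4.07e-10), and Klf1 at least 91.2-fold lower. In all, 5188 genes differed, 2587 higher and 2601 lower, of which 1514 and 1648 by at least 2-fold, and 972 folds are known only as bounds. Median scaling gave 40.5% of 4491 called genes as higher, against 49.9%.

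B lineage genes were higher for 27 of 28 and lower for 0 in CD31+ B220+ cells (27 and 0 adjusted over the list alone; adjusted p = 6.41e-20). Cd72 was at least 212-fold and Rag1 at least 34.1-fold higher. MHC class II genes were higher for 11 of 11 (11 adjusted over the list alone; adjusted p = 8.22e-08, and adjusted p = 0.117 with an estimated correlation). H2-Ob was at least 50.3-fold higher. Plasmacytoid dendritic cell genes were higher for 13 of 22 and lower for 2 (13 and 2 adjusted over the list alone; adjusted p = 0.000198, and adjusted p = 0.139 with an estimated correlation). Erythroid genes were lower for 29 of 29 (29 adjusted over the list alone; adjusted p = 9.52e-21). Tspan33 was at least 88-fold lower. Stromal genes were lower for 20 of 28 and higher for 1 (21 and 1 adjusted over the list alone; adjusted p = 4.5e-09, and adjusted p = 0.0978 with an estimated correlation). Bgn, biglycan, was at least 17.4-fold and Col5a1 at least 36.4-fold lower. Macrophage genes were lower for 23 of 28 and higher for 0 (23 and 0 adjusted over the list alone; adjusted p = 9.73e-12, and adjusted p = 0.0789 with an estimated correlation). Slc40a1, the iron exporter, was 28.9-fold lower. Neutrophil genes were lower for 24 of 28 and higher for 0 (24 and 0 adjusted over the list alone; adjusted p = 7.68e-10, and adjusted p = 0.172 with an estimated correlation).

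Scavenger receptors were lower for 9 of 15 and higher for 0 in CD31+ B220+ than in CD31- B220- cells (10 and 0 adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.0785 with an estimated correlation). Stab1, a scavenger receptor of sinusoids and macrophages, was 2.89-fold lower. Cell cycle genes were lower for 38 of 41 and higher for 0 (39 and 0 adjusted over the list alone; adjusted p = 1.25e-12, and adjusted p = 0.187 with an estimated correlation). Tk1, thymidine kinase, was 7.73-fold lower. Lysosome genes were lower for 19 of 37 and higher for 4 (21 and 6 adjusted over the list alone; adjusted p = 0.00743, and adjusted p = 0.479 with an estimated correlation). Interferon response genes were lower for 12 of 27 and higher for 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0329, and adjusted p = 0.561 with an estimated correlation). Rsad2 was 15.2-fold lower. Without CD31- B220- replicate 3, erythroid genes were lower for 28, stromal for 22, macrophage for 21, cell cycle for 39 and interferon genes for 10.

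No call was made for the other 11 lists (adjusted p from 0.0893 to 0.862). Counts higher and lower were 3 and 1 of 5 for sorting-marker, 1 and 5 of 15 for sinusoidal endothelial, 3 and 6 of 25 for pan-endothelial and 8 and 9 of 32 for stem cell genes, 6 and 4 of 18 for transition transcription factors and 4 and 2 of 13 for plasma cell genes. They were 6 and 6 of 18 for conventional dendritic cell, 1 and 3 of 15 for basophil and mast cell, 0 and 5 of 21 for megakaryocyte, 3 and 4 of 21 for T and NK cell and 11 and 7 of 24 for immediate early genes. Adjusted over the list alone, transition factors were at 6 and 5, T and NK cell genes at 3 and 3, immediate early genes at 11 and 8 and the others as before. T and NK cell genes had a median of -0.11 and a mean of 0.05. Plasma cell genes passed under median scaling (adjusted p = 0.0452; 0.0452 to 0.186 over 5 alternatives).

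Camera made 77 calls over the 132 tests of lists, and 26 of these held with an estimated correlation. These were the pan-endothelial, stem cell and megakaryocyte lists in each comparison with HSC, the B lineage and plasma cell lists for CD31+ B220+ and for CD31+ B220- cells against HSC, the conventional dendritic cell list for CD31+ B220- cells and the erythroid list for CD31- B220- cells against HSC. Between CD31+ B220+ and CD31+ B220- cells they were the scavenger receptor, sinusoidal, pan-endothelial, B lineage, macrophage, basophil and mast cell, and megakaryocyte lists. Between CD31+ B220- and CD31- B220- cells they were the basophil and mast cell and the erythroid lists, and between CD31+ B220+ and CD31- B220- cells the B lineage and the erythroid lists.

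**Figure D4:**
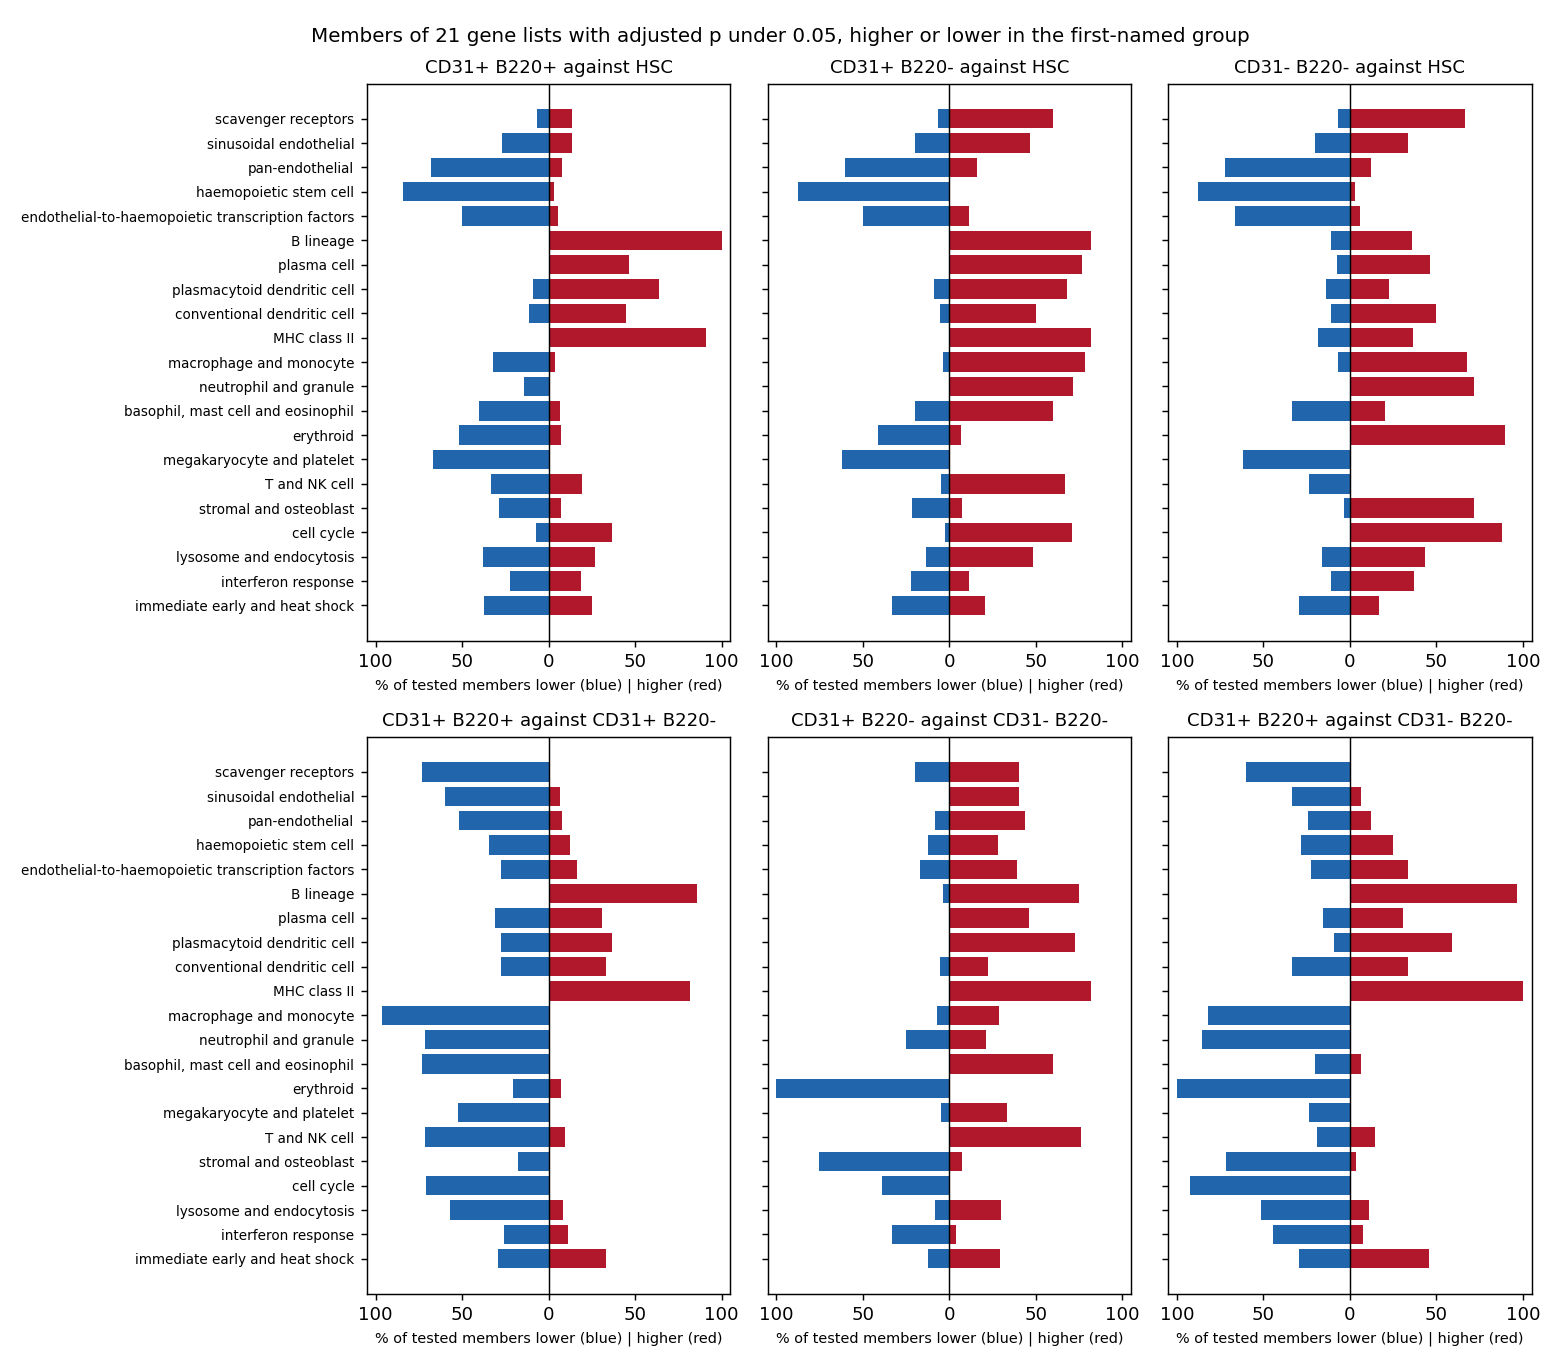
Percentage of the tested members of 21 gene lists that were higher (red) or lower (blue) in the first-named group, with 1 panel for each of the 6 comparisons. Erythroid genes were lower for 29 of 29 between CD31+ B220- and CD31- B220- cells; under median scaling the majority turned for the scavenger receptors and cell cycle genes of CD31+ B220+ cells, the sinusoidal and lysosome genes of CD31+ B220- cells, and the sinusoidal, plasmacytoid dendritic cell, MHC class II, lysosome and interferon genes of CD31- B220- cells, each against HSC.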

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

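The tests of scanner gain, of expression-matched lists, of dilution of endothelial cells, of mixed cell types and of free RNA were chosen only after the results were seen, and the tests of labelled RNA yield, of the list's gap under each scaling and of other splits before. The HSC arrays were brighter than the 9 others. Over 5800 genes detected on all arrays, the median ratio of background-subtracted signal was 4.4, falling from 5.49 for the dimmest genes to 3.2 for the brightest, while 509 background probes had a ratio of 1.06, which argues against scanner gain. Labelled RNA yield or quality may still be a cause, because 50 ribosomal protein genes had a ratio of 2.71. It cannot be told apart from cell type, since every bright array is an HSC array, and a biological difference in RNA content was not tested.

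Pan-endothelial genes were lower in all 3 fractions than in HSC, although the labels call the fractions endothelial. Of 25 tested list genes, 19 were detected on both HSC arrays. Every array of the fraction detected 15 in CD31+ B220-, 9 in CD31- B220- and 3 in CD31+ B220+ cells. Many list genes were thus expressed in HSC, so the list's direction may reflect their level in HSC as much as in the fractions. The smallest gap between the list median and the all-gene median, over 3 comparisons and 5 scalings, was -0.55. Resampling the list genes gave it a 95% bootstrap interval of -1.98 to -0.15. The gap was past the bound of -0.5 but not beyond this spread among genes. The interval was taken for the smallest gap only and held the arrays fixed, so it does not measure spread between arrays. Against 10000 random lists matched for expression, the list median fell at percentile 0.01, the lowest that 10000 lists can give, in all 3 comparisons and 5 scalings, which argues against scaling of the arrays as the whole cause. Dilution of endothelial cells by other cells might contribute and stays open: of 5 list genes that no HSC array detected, 4 were detected on all 3 CD31+ B220- arrays, and 0 lay above the median of tested genes there. A true difference in endothelial identity was not tested and stays open too.

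Transcripts of several blood and stromal lineages appeared in the fractions. Free RNA carried evenly into every sort would leave list medians within 1 log2 of each other. Medians over the genes' fraction means differed between fractions by 5.54 for B lineage, 6.07 for erythroid, 3.66 for macrophage, 4.34 for neutrophil, 1.85 for basophil and mast cell, 2.94 for T and NK cell and 2.89 for stromal genes. List medians taken on each array, a different measure, were at least 1.97 apart between arrays of the highest and lowest fraction in each list. Both measures argue against an even carry-over of free RNA as the whole source of these lists. The bound of 1 replaced a bound of 2 after these values were known, and under the bound of 2 the basophil and mast cell list and the T and NK cell list (1.99 between the closest arrays) stayed open, as globins do under both (1.21, and 0.66 between the closest arrays); an uneven carry-over was not tested. A mixture of cell types in a gate is a candidate explanation: in 6 of 7 lineage lists members varied together between replicates beyond matched random lists, from 0.559 for neutrophil to 0.159 for erythroid genes, with basophil and mast cell genes at 0.052 below their 95th percentile of 0.091. The B220- gates would remove B220+ B cells, yet Cd79b, of the B lineage list, averaged 11.23 in CD31+ B220- cells. No label names a depletion of other lineages for the fractions. In CD31+ B220- cells the highest list medians were 8.86 for macrophage, 8.79 for neutrophil, 8.42 for B lineage and 7.85 for T and NK cell genes. In CD31- B220- cells they were 11.55 for erythroid, 9.46 for neutrophil and 7.83 for stromal genes. The lowest detected values were 5.19 to 5.45. Such levels argue against a single cell type of varying state in these gates, if carry-over was even. In CD31+ B220+ cells B lineage genes were at 10.98 and the other lists at 4.91 to 5.48, so a single cell type stays open there.

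In 1 of 100 drawn splits of the 9 arrays of the fractions, the real one, 6056 genes differed, and the highest of the others gave 2917. This is the lowest share that 100 splits can give, and it argues against chance for that count. The test takes the arrays as independent, which the labels do not state. For the comparisons of 3 against 3 arrays, the real split was the 1 of 10 with as many genes; the counts were 4142, 3345 and 5188 and the highest other was 0 in each, and 10 splits are too few for a share under 0.05.

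Among 10396 probes without a single gene name used here, which are not among the 11376 tested genes, 2872 were detected on every array of at least 1 group. The 3811 detected on at least 2 arrays were tested, and 1385 of these differed among the fractions. Called in the comparisons with HSC were 1545 of them for CD31+ B220+ (818 higher), 1293 for CD31+ B220- (572 higher) and 1483 for CD31- B220- cells (714 higher). Between CD31+ B220+ and CD31+ B220- cells 1018 were called, 638 of them higher in the first, while of 4142 called genes 1981 were higher. Between CD31+ B220- and CD31- B220- cells 580 were called (318 higher in the first), and between CD31+ B220+ and CD31- B220- cells 1219 (699 higher in the first). More than 1 of these probes can belong to the same gene, so the counts of probes and genes were not added.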

How the results depend on the processing

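Among the alternatives, the list counts without CD31- B220- replicate 3 were chosen after the data were seen. Of 13603 values for 592 named-gene results, 13452 kept their direction and side of the threshold, 142 lost a call (75 of them with a minimum log2 change of 1), 6 gained one and 3 reversed. The 3 that reversed did so under median scaling: Birc5 in CD31+ B220+ cells at -0.042, Pecam1 in CD31+ B220- cells at -0.845 and Ptprc in CD31+ B220+ cells at -0.598, each against HSC. Apart from the sorting-marker genes, these results were calls picked in these data for large changes or small adjusted p. Their calls were therefore likely to hold. Of all called genes, median scaling kept 77.8%, 76.6% and 76.9% as called, in either direction, against HSC for CD31+ B220+, CD31+ B220- and CD31- B220- cells. Between fractions it kept 77.2% to 82.4%. Median scaling also raised the genes called to 8374 for CD31+ B220+ and 8232 for CD31+ B220- cells against HSC. It aligns the median probe, which is undetected on every array, so detected genes of the brighter HSC arrays shift. A minimum log2 change of 1, stricter by construction, left 1484, 1125 and 1753 genes against HSC in the order CD31+ B220+, CD31+ B220-, CD31- B220-, then 866 for CD31+ B220+ against CD31+ B220-, 678 for CD31+ B220- against CD31- B220- and 1649 for CD31+ B220+ against CD31- B220-. The replicate block gave 4969, 4570, 5509, 4081, 3239 and 5158, and 5959 among the fractions. Of 9 arrays, 3 correlated best with their own number after group means were removed. These correlations ran from -0.09 to 0.2 for pairs of the same number and from -0.17 to 0.17 for the others. No pairing by number was seen, but so few arrays cannot exclude it. Leaving out 1 array gave 3727 to 5331, 3252 to 5023 and 4289 to 5760 against HSC, 3416 to 4276, 2650 to 3586 and 4653 to 5213 between fractions, and 5428 to 6103 among them; with 1 HSC array left, that array is assumed to vary like the other groups. Of 660 values for 132 list results, 595 were the same, 59 lost a call (51 with an estimated correlation), 6 gained one and 0 reversed. Direction here is that of camera, a list against all other tested genes. Counts of members higher and lower did turn for some lists under median scaling. The 6 gained were under median scaling B lineage (5.64e-05), plasmacytoid dendritic cell (0.0473) and, for CD31+ B220- cells, sinusoidal genes (0.0177) against HSC, plasma cell genes between CD31+ B220+ and CD31- B220- cells (0.0452), and with the deposited values B lineage (0.0279) and lysosome genes (0.0491) of CD31- B220- cells; the causes were not tested. A block by bead chip was not run. Dim genes limit the folds: 503 to 1244 per comparison are bounds. Among named and list genes, the chosen probe and another probe of the same gene were both called in 883 cases. In 15 of these, in 6 genes, the directions were opposite. Scarb2, a scavenger receptor, was at 1.8 and -1.34 in CD31+ B220- cells and at 1.73 and -1.38 in CD31- B220- cells, each against HSC. The alternative of all probes singly kept the probe with the smallest adjusted p, so it does not show such conflicts.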

Other observations

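The genes named here were chosen after their values were seen. Stab1 averaged 10.38 ± 0.32 (n = 3) in CD31+ B220- cells, 10.33 ± 0.02 (n = 3) in CD31- B220- cells and 8.80 ± 0.57 (n = 3) in CD31+ B220+ cells. Stab2 was detected on all 3 CD31+ B220- arrays, at 5.99 ± 0.32 (n = 3), and on no array of the CD31+ B220+ and CD31- B220- fractions. It did not pass the stricter filter of detection p under 0.01 on at least 3 arrays. Cdh5, which encodes VE-cadherin, was at 5.72 ± 0.16 (n = 3) in CD31+ B220- cells and undetected on every HSC and CD31- B220- array. The lowest detected values on the CD31+ B220- arrays were 5.19 to 5.32, so Stab2 and Cdh5 lay near the floor. Flt1, a receptor for VEGF, averaged 7.72 ± 0.73 (n = 3) in CD31- B220- cells and 6.43 ± 0.24 (n = 3) in CD31+ B220- cells. Cxcl12, the chemokine that holds stem cells in the marrow, averaged 11.73 ± 0.36 (n = 3) in CD31- B220- cells and 6.81 ± 1.58 (n = 3) in CD31+ B220- cells.

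Hba-a1, Hbb-bs and Hbb-bt, 3 globin genes chosen after their values were seen, averaged 14.21 in HSC, 13.2 in CD31+ B220+, 13.24 in CD31+ B220- and 14.41 in CD31- B220- cells, and ran from 12.37 to 14.71 over all arrays. The median of 25 other erythroid genes was 6.75 in HSC, 5.37 in CD31+ B220+, 5.91 in CD31+ B220- and 11.28 in CD31- B220- cells. High globin signal outside CD31- B220- cells thus came without like levels of these genes. The raw globin signals were 14.1% to 94.6% of the highest signal on the array. Those highest signals ran from 20082.9 to 42391.1 between arrays, so the shares do not show whether globin signals were saturated.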
